A study of Mus musculus with 12 samples.

How the data were processed

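RNA was measured in 12 samples of cultured splenic mouse NK cells in 4 groups, PKM2 WT, PKM2 KO, vehicle and TEPP-46, with 3 replicates each in the labels. The PKM2 WT animals carried Cre from the Ncr1 gene and the PKM2 KO animals the same Cre with floxed PKM2 alleles, per the labels. The sources give the TEPP-46 dose as 50 µM in one place and 50 mM in another, and name the vehicle as DMSO at 0.1% in one place and as PBS in another. They name a poly(A)-selected stranded library kit in one place and total RNA in another, and the non-polyadenylated RNAs Rn7s1, Rn7s2 and Rn7sk together made up between 32.4% and 56.2% of the summed RPKM of each library. That share was higher in the genotype libraries than in those of the drug experiment.

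Reads were aligned with STAR to the mm10 build, per the submitters' processing notes; versions, read counting and annotation are not given in the sources used here. The authors deposited RPKM, reads scaled by gene length and by mapped reads, for 11706 genes, rounded to 2 decimals. The authors deposited tables with the mean ratio (fold) between groups and its p-value for the genes they listed, and these are quoted as the authors' values only; how they were computed is not given in the sources used here. In the RPKM table, 11 columns matched a sample by name and were used. No column matched PKM2 KO replicate 3, which was not analysed here, so PKM2 KO had 2 libraries and not 3. A further 5 columns of libraries matched no sample and were not used.

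Gene IDs were matched without their version to the GENCODE M21 annotation of GRCm38, the same assembly as mm10. Of 11706 IDs 11675 matched and 31 did not. Names in the authors' tables were also looked up through older symbols. Coordinates are 1-based.

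From the RPKM, log2(RPKM + 1) was computed for the 11142 genes with a mean of at least 1 RPKM over the 11 libraries. No further scaling was applied. Fold changes are on this log2(value + pseudocount) scale and understate changes of low genes. An RPKM of exactly 0 can be a failed estimate, so such genes are given by library, with no fold; a fitted value of 1 of them, Mir6374, is given only with its dependence on the pseudocount. Genes were tested with limma 3.58.1 in R 4.3.3, with the trend of the variance on the mean, and Benjamini-Hochberg adjustment; the threshold was an adjusted p of 0.05. The genotype and drug comparisons used only the libraries of the 2 groups compared. The comparison of PKM2 WT with vehicle and that of the 2 effects used 4 group means over all 11 libraries. Permutation tests were exact and two-sided; 3 against 2 libraries and 3 against 3 cannot go below p = 0.1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

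Gene lists (42 of them, covering metabolism, stress, growth, NK cell function, RNA quality and other cell types) were fixed before the data were examined, and the 38 with at least 5 tested members were tested with camera at a preset correlation of 0.01. For each list the members passing over all genes and those passing when adjusted over the list alone were counted. Camera with an estimated correlation and fry were run beside it. No list passed with an estimated correlation in either comparison. Fry's directional test asks whether a list's genes move on balance one way, and does not compare the list with other genes. In no list past the threshold did the median differ in sign from the test.

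The text names Pkm and Ncr1, the 12 higher and 12 lower genes with the largest change past the threshold whose groups do not overlap, the 10 genes with the smallest p where fewer than 5 pass, up to 4 members per list with the smallest p, and the 5 higher and 5 lower genes with the largest fold in each of the authors' tables. Genes named outside this rule are said to be so. The values of 1 gene that the rule names are not reported here.

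The labels do not say from how many animals each culture came, so p-values measure the spread between these libraries, which may be partly technical. Total reads per library are not given. Whether the RPKM steps of short, low genes reveal the relative depth was checked on genes under 300 bases. At most 7 of 160 to 183 such genes shared one ratio between libraries, with a tolerance of 0.0015 in the natural log, so depth stayed unknown and no counting interval is given.

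Each test was checked on simulated data for 11142 genes with 200 changed by known folds. For PKM2 KO against PKM2 WT it recovered 40.3% of genes changed 1.5-fold, 80.6% of those changed 2-fold and 90.9% of those changed 4-fold, with 10 unchanged genes called. For TEPP-46 against vehicle it recovered 58.2%, 88.1% and 97.0%, with 3 unchanged genes called. For the difference of the effects it recovered 49.3%, 89.6% and 98.5%, and for PKM2 WT against vehicle 71.6%, 89.6% and 100%. The simulated genes were independent, with a spread pooled over all libraries, and those changed had a mean log2(RPKM + 1) above 3. With 200 genes changed at once the adjusted threshold is easier to pass than with few. These shares therefore need not hold for low genes or where few genes change, and a gene not called may still have changed. A list moved by 0.5 on the log2 scale was found and 0 of the other lists were. As genes were drawn independently there, this does not check the list calls where members of a list are correlated. The shift was also larger than any list median under TEPP-46, the largest being 0.24.

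Alternatives covered the pseudocount, the filter, median-ratio rescaling, quantile normalization, the variance model, library weights, the replicate number as a block, a fold threshold, the spread from all libraries and leaving out each library; leaving out a PKM2 KO library leaves 1, which is assumed to vary like the other libraries of the fit. A test on counts could not be run on RPKM. Testing only protein-coding genes and adding the animals' sex, read from Xist and Y-linked genes, were chosen after seeing the data.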

Results

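RNA was sequenced from cultured mouse natural killer (NK) cells, lymphocytes that kill infected and tumour cells without prior sensitisation. The cells were isolated from spleen, grown for 6 days in IL-15 at 10 ng per mL and, per the labels, then kept for 18 hours with IL-2 at 330 U per mL and IL-12 at 10 ng per mL, cytokines that activate them. A genotype experiment held NK cells with (PKM2 WT, n = 3) and without (PKM2 KO, n = 2) the M2 isoform of pyruvate kinase, a glycolytic enzyme, the deletion being driven by Cre from the NK cell gene Ncr1. A drug experiment held cells given the PKM2 activator TEPP-46 (n = 3) or vehicle (n = 3). Values were RPKM for 11706 genes, of which 11142 averaged at least 1 RPKM over the 11 libraries and were tested. The read depth behind each value is unknown. The median tested gene lay between 13.2 and 14.4 RPKM in each library. Log2 values of libraries of the same group correlated across genes with r from 0.959 to 0.980, those of different groups of the same experiment with r from 0.957 to 0.983, and those of different experiments with r from 0.840 to 0.878; genes are not independent replicates.

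The targeted gene was read first. Pkm (ENSMUSG00000032294, chromosome 9, 59656368 to 59679375, GRCm38) encodes both the M1 and the M2 isoform, and was measured as a whole gene. It stood at 206 ± 12.7 RPKM (SD, n = 3) in the libraries labelled PKM2 WT and at 77.5 ± 1.27 RPKM (SD, n = 2) in those labelled PKM2 KO, a ratio of means of 0.377. Its log2 fold change was -1.40 with an SE of 0.07 (limma adjusted p = 0.00847), lower in 2 of 2 PKM2 KO libraries. An exact two-sided permutation test over the 10 arrangements gave p = 0.1, the smallest this design allows. Pkm differed by less than the spread between replicates under TEPP-46, at 1099 ± 51.8 RPKM (SD, n = 3) against 1085 ± 107 RPKM (SD, n = 3) in vehicle, with a 95% interval of the log2 difference from -0.19 to 0.24. Ncr1 (ENSMUSG00000062524), the gene of the NK receptor NKp46, stood at 238 ± 2.90 RPKM (SD, n = 3) in PKM2 WT and 245 ± 18.3 RPKM (SD, n = 2) in PKM2 KO.

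The libraries labelled PKM2 WT and the vehicle libraries, both labelled as cultured with IL-2 and IL-12, were far apart. Ifng, the gene of interferon gamma, the main cytokine of activated NK cells, was at 23.4 ± 0.732 RPKM (SD, n = 3) in the libraries labelled PKM2 WT and at 1044 ± 35.6 RPKM (SD, n = 3) in vehicle. Il2ra, the high-affinity IL-2 receptor chain, was at 3.73 ± 0.172 against 33.6 ± 3.22 RPKM (SD, n = 3 each). The killing protease gene Gzmb was at 2753 ± 131 against 14777 ± 789 RPKM, the lactate dehydrogenase gene Ldha at 233 ± 21.6 against 1214 ± 102 RPKM and the proliferation marker Mki67 at 57.7 ± 3.65 against 146 ± 4.45 RPKM (SD, n = 3 each). Pkm was lower by a log2 fold change of -2.39 (SE 0.08, limma adjusted p = 9.32e-09), and Ncr1 was higher by 1.28 (SE 0.10, limma adjusted p = 1.77e-06). Ifng, Il2ra, Gzmb, Ldha and Mki67 were chosen here after their values were seen.

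In all, 4088 genes were higher and 4299 lower in the libraries labelled PKM2 WT than in vehicle, of 11142 tested with limma, and 5019 of these differed by at least 1.5-fold on the log2(RPKM + 1) scale. The experiment (cell culture, animals and library preparation) and the group cannot be told apart in this comparison. In the libraries labelled PKM2 KO, Ifng was between 18.8 and 24.3 RPKM, so directions drawn from the genotype experiment below hold for libraries with low Ifng, whatever their labels state.

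**Figure D1:**
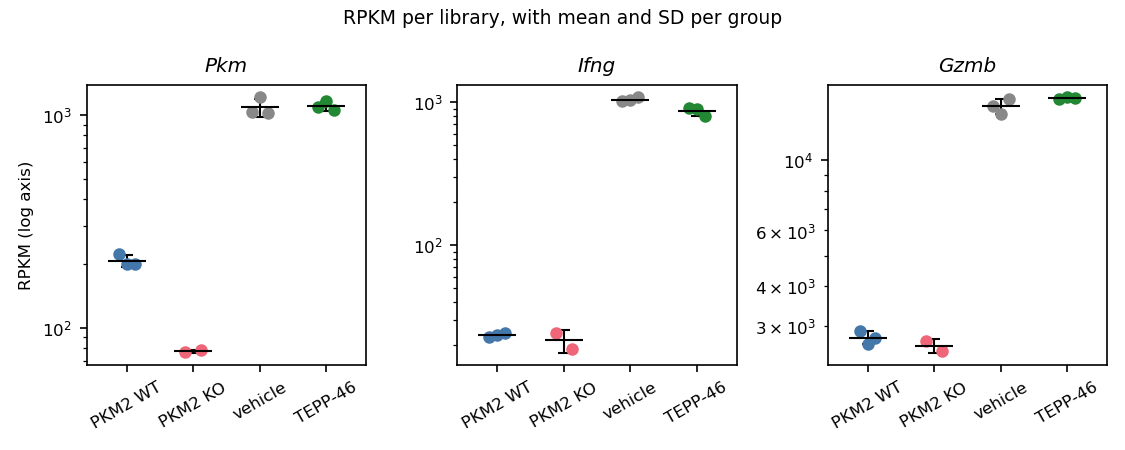
RPKM (log axes) of Pkm, Ifng and Gzmb in each of the 11 libraries, one point per library, with the group mean and SD as a bar. Ifng lies between 18.8 and 24.3 RPKM in the 5 genotype libraries and at 797 RPKM or more in the 6 libraries of the drug experiment.

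The genotype comparison asks which transcripts depend on PKM2 in NK cells. Cell cycle genes were lower together in the libraries labelled PKM2 KO. All 35 measured members of the mitosis list had log2 fold changes below 0, with a median of -0.67, and the list fell (camera adjusted p = 1.58e-31; adjusted p = 0.672 with an estimated correlation). None of the 35 passed over all genes tested, and 34 were lower when adjusted over the list alone. Mki67 was at 38.4 ± 0.375 RPKM (SD, n = 2) in PKM2 KO against 57.7 ± 3.65 (SD, n = 3) in PKM2 WT, and Tacc3, which stabilises spindle microtubules, at 13.4 ± 0.262 against 23.3 ± 1.94 RPKM. Cenpe, a kinetochore motor, was at 7.46 against 11.8 RPKM, and Hmmr, a spindle-associated protein, at 6.83 against 11.8 RPKM.

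The DNA replication list fell as well, with all 36 measured members below 0 and a median log2 fold change of -0.44 (camera adjusted p = 6.85e-17; adjusted p = 0.672 with an estimated correlation). None of its members passed over all genes, and 1 was lower adjusted over the list alone. Ccne2, the cyclin E2 gene, was at 6.83 against 14.5 RPKM, Cdc6, a licensing factor, at 2.93 against 5.63 RPKM and Mcm10, a replication initiation factor, at 3.56 against 8.41 RPKM. The canonical histone genes, a list fixed among those of RNA quality, fell with a median of -0.51 in 13 of 13 members (camera adjusted p = 1.68e-06; adjusted p = 0.672 with an estimated correlation), with 0 passing over all genes or adjusted over the list alone. Hist1h4h was at 251 against 396 RPKM.

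Lists of metabolism, of MYC targets and of mitochondrially encoded genes, the last fixed among those of RNA quality, moved less. The nuclear-encoded respiratory chain list had 62 of 71 members below 0 (median -0.07, camera adjusted p = 3.11e-05), the sterol and fatty acid synthesis list 28 of 32 (median -0.09, adjusted p = 0.000484), the tricarboxylic acid cycle list 21 of 26 (median -0.06, adjusted p = 0.00981), the mitochondrially encoded genes 13 of 13 (median -0.22, adjusted p = 0.0105) and the MYC target list 29 of 40 (median -0.06, adjusted p = 0.00662). Each of these 5 had an adjusted p = 0.672 with an estimated correlation, and no member passed over all genes. Dlat, a subunit of pyruvate dehydrogenase, was the 1 member lower adjusted over the list alone, at 10.6 against 16.5 RPKM. Dlat lies within 20 Mb of Pkm on chromosome 9, among the genes of small p near Pkm that are flagged below. An effect of losing PKM2 on Dlat was not tested apart from one of a linked segment. The respiratory chain and tricarboxylic acid cycle lists no longer passed without PKM2 WT replicate 1 (adjusted p = 0.189 and 0.114; median -0.024 for the former), nor did the mitochondrially encoded genes without PKM2 WT replicate 3 or PKM2 KO replicate 2 (adjusted p = 0.140 and 0.219, median -0.05 and -0.14; the latter fit has 1 PKM2 KO library) or the MYC target list with the spread from all 11 libraries (adjusted p = 0.105). The sterol and fatty acid synthesis median was -0.17 without PKM2 WT replicate 2 and -0.15 without PKM2 KO replicate 2, and quantile normalization gave medians of -0.030, -0.029 and -0.035 for the tricarboxylic acid cycle, respiratory chain and MYC target lists.

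The glycolysis list, which holds genes of Pkm's pathway but not Pkm itself, did not pass (21 members measured, 11 above and 10 below 0, median 0.02 with a mean on the other side of 0, camera adjusted p = 0.790). None of its members passed over all genes or adjusted over the list alone. Slc2a1, the glucose transporter GLUT1, was at 10.1 ± 0.354 RPKM (SD, n = 2) in PKM2 KO and 9.23 ± 0.389 (SD, n = 3) in PKM2 WT, and Aldoa at 419 against 395 RPKM. The NK receptor list (median 0.00, 22 of 43 above 0, camera adjusted p = 0.902) and the cytotoxic effector list (median 0.07, 12 of 19 above 0, adjusted p = 0.0628) did not pass either.

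Among the tested lists of other cell types, only that of granulocytes, basophils and mast cells passed. The T cell list (camera adjusted p = 0.421), the dendritic cell list (0.817) and that of ILC1 and helper innate lymphoid cells (0.601) did not. The granulocyte, basophil and mast cell list fell, with 7 of 7 members below 0 and a median of -0.93 (camera adjusted p = 0.000484; adjusted p = 0.672 with an estimated correlation), 0 of them passing over all genes or adjusted over the list alone. The median was -0.58 without PKM2 WT replicate 3. Mcpt8, a basophil protease gene, was at 29.6 ± 12.9 RPKM (SD, n = 2) in PKM2 KO and 62.5 ± 33.5 (SD, n = 3) in PKM2 WT, and Fcer1a, an IgE receptor chain, at 4.21 against 9.04 RPKM. The animals' sexes were mixed within both groups, PKM2 WT replicate 3 and PKM2 KO replicate 2 expressing the Y-linked gene Ddx3y at 39.0 and 36.2 RPKM and the other 3 libraries listing it at 0.

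Over all genes, 11 differed between the libraries labelled PKM2 KO and PKM2 WT, 2 higher and 9 lower (limma, Benjamini-Hochberg adjusted p under 0.05). Only Pkm and Slc15a2 of these are protein-coding. Slc15a2, a transporter of small peptides (ENSMUSG00000022899, chromosome 16, 36750177 to 36784962), was at 35.3 ± 2.14 RPKM (SD, n = 3) in PKM2 WT and 0.0900 ± 0.0141 (SD, n = 2) in PKM2 KO, with a log2 fold change of -5.06 (SE 0.08, limma adjusted p = 0.000244; -7.54 with a pseudocount of 0.1 and -2.99 with 5), and was at 1.93 RPKM in vehicle. The other 9 are short non-coding genes, of which 8 were listed at 0 in every library of one group. Mir6374 was at 18.7, 13.5 and 26.9 RPKM in PKM2 WT and listed at 0 in the other 8 libraries, and Gm23455 at 162, 110 and 290 RPKM in PKM2 WT and at 0 in both PKM2 KO libraries. Gm25827 (37.5, 54.0 and 40.4 RPKM), Gm26226 (31.2, 23.8 and 23.5), Snord8 (30.4, 33.5 and 22.2) and Gm22372 (3.93, 3.31 and 3.22) were likewise listed at 0 in both PKM2 KO libraries. Gm23925 and Gm26004 were listed at 0 in the 3 PKM2 WT libraries, and stood at 83.4 and 34.3 RPKM and at 12.3 and 16.5 RPKM in PKM2 KO. Snora61 was at 42.9, 40.0 and 26.7 RPKM in PKM2 WT and 3.97 and 4.08 in PKM2 KO. Reads of short non-coding genes can be shared with near-identical copies, which was not tested for these 9, so their values are uncertain.

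The count was 7 (1 higher, 6 lower) with a pseudocount of 5, 6 (1 higher, 5 lower) with the animals' sex as a covariate and 5 (all lower) without PKM2 WT replicate 2. With the spread taken from all 11 libraries 25 genes passed (4 higher, 21 lower), among them 4 of the 11. Leaving out a PKM2 KO library leaves 1, assumed to vary like the PKM2 WT libraries, which alone give the spread. Such fits gave 21 genes (16 higher, 5 lower) without PKM2 KO replicate 2 and 11 (7 higher, 4 lower) without PKM2 KO replicate 1, among them 6 and 5 of the 11 genes above.

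The Pkm call missed the threshold without PKM2 WT replicate 2 (limma adjusted p = 0.0596) and with sex as a covariate (adjusted p = 0.0618), as well as with a single PKM2 KO library (adjusted p = 0.108 without PKM2 KO replicate 1 and 0.0728 without PKM2 KO replicate 2), its log2 fold change staying between -1.42 and -1.38 in these 4 fits. Leaving out 1 PKM2 WT library, Slc15a2, Gm25827, Gm26226 and Snord8 passed each time, whereas the other 6 small RNAs each missed the threshold at least once, Snora61 with an adjusted p of 0.163 without PKM2 WT replicate 1 and 0.320 without PKM2 WT replicate 2, and Gm23925 without any of the 3 PKM2 WT replicates (0.163, 0.242 and 0.183). With a single PKM2 KO library Snord8 had an adjusted p of 0.0570 without PKM2 KO replicate 1 and 0.0353 without PKM2 KO replicate 2, and Snora61 0.402 and 0.313.

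Of the 11 genes in the authors' deposited table for the knockout, 7 were in the expression table under the same or an older symbol, all 7 in the direction of the authors' deposited table and 1 of them, Pkm, past the threshold. Cd3g, a chain of the T cell receptor complex, was at 7.90 RPKM in vehicle. It was at 10.5 ± 5.78 RPKM (SD, n = 2) in PKM2 KO and 85.0 ± 15.2 (SD, n = 3) in PKM2 WT (log2 fold change -2.98, SE 0.35, limma adjusted p = 0.228). Dixdc1, a Wnt pathway gene, was at 10.4 against 28.9 RPKM (adjusted p = 0.310), Nlrx1, a mitochondrial NOD-like receptor, at 0.455 against 2.45 RPKM (adjusted p = 0.124) and Slc37a4, the glucose-6-phosphate transporter, at 4.89 against 5.78 RPKM (adjusted p = 0.610). Amica1, listed as Jaml in the authors' deposited table and encoding an adhesion molecule, was at 39.0 ± 1.31 RPKM in PKM2 KO and 22.9 ± 1.32 in PKM2 WT (adjusted p = 0.108). With only protein-coding genes tested, a choice made after seeing the data, 5 of the 7 passed.

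**Figure D2:**
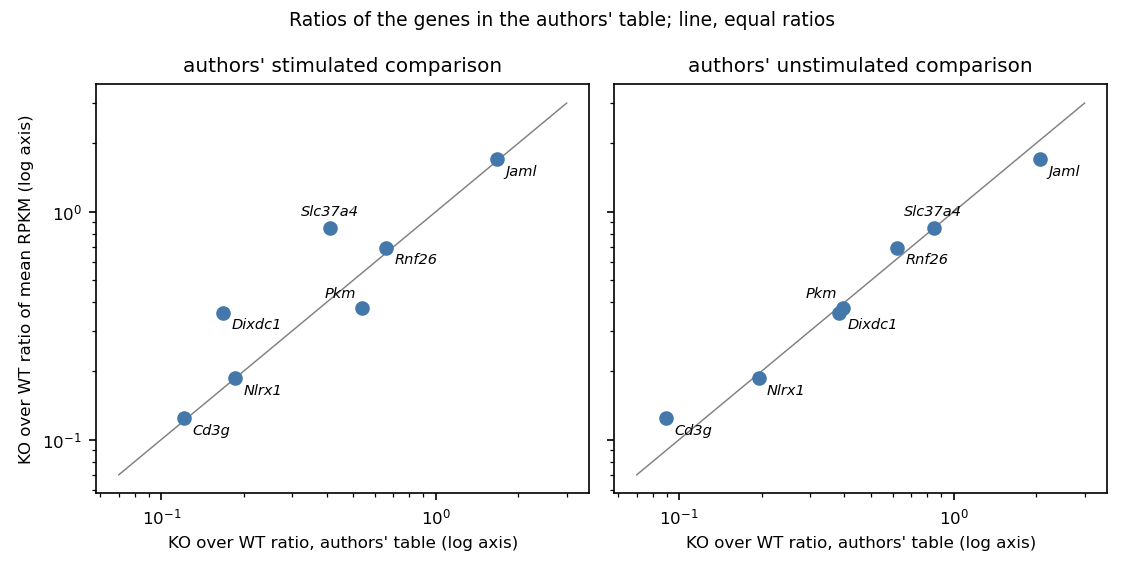
Ratio of mean RPKM, PKM2 KO over PKM2 WT, of 7 genes (vertical, log axis) against the ratio in the authors' deposited table (horizontal, log axis) for their stimulated (left) and unstimulated (right) comparison; the line marks equal ratios. Slc37a4 stands at 0.847 here, and in the authors' deposited table at 0.411 in the stimulated and 0.845 in the unstimulated comparison.

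The drug comparison asks what activating PKM2 does to cytokine-stimulated NK cells. Lists of NK identity and killing were higher in the TEPP-46 libraries, and lists of lipid synthesis, ribosomal proteins, mitosis and MYC targets lower, by small amounts, while the DNA replication list did not pass. The NK receptor and adhesion list rose, with 38 of 43 measured members above 0 and a median log2 fold change of 0.21 (camera adjusted p = 1.64e-18; adjusted p = 0.229 with an estimated correlation). None of the 43 passed over all genes, and 18 were higher adjusted over the list alone. Klra8, the activating receptor Ly49H, was at 204 ± 1.62 RPKM (SD, n = 3) under TEPP-46 and 162 ± 5.93 (SD, n = 3) in vehicle. Klra5, another Ly49 receptor gene, was at 29.3 against 21.9 RPKM, and Klrg1, a marker of mature NK cells, at 22.2 against 16.1 RPKM. Reads of the Klra genes can be shared between near-identical members of the family.

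The cytotoxic effector list rose, with 16 of 19 members above 0 and a median of 0.24 (camera adjusted p = 2.43e-09; adjusted p = 0.229 with an estimated correlation). None passed over all genes and 10 were higher adjusted over the list alone. Gzmf was at 44.4 ± 6.31 RPKM (SD, n = 3) under TEPP-46 and 14.04 ± 2.68 (SD, n = 3) in vehicle, Gzme at 458 ± 62.0 against 207 ± 38.4 and Gzmd at 763 ± 114 against 349 ± 60.5 RPKM, 3 neighbouring granzyme genes on chromosome 14. Fasl, the death ligand, was at 109 ± 3.15 against 86.2 ± 2.26 RPKM. Ifng stood at 867 ± 61.3 RPKM under TEPP-46 and at 1044 ± 35.6 in vehicle (log2 fold change -0.27, SE 0.07, limma adjusted p = 0.372), and the cytokine and chemokine list did not pass (7 of 19 above 0, median -0.05, camera adjusted p = 0.710).

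The NK transcription factor list rose, with 22 of 30 members above 0 and a median of 0.08 (camera adjusted p = 0.000149; adjusted p = 0.229 with an estimated correlation), with 0 passing over all genes and 5 higher adjusted over the list alone. Myb was at 14.1 against 9.96 RPKM, Id2, which NK cells need to develop, at 686 against 574 and Irf8 at 319 against 257 RPKM. Interferon-stimulated genes (28 of 36 above 0, median 0.09, camera adjusted p = 7.36e-05; adjusted p = 0.275 with an estimated correlation) and NF-kB targets (16 of 23, median 0.05, adjusted p = 0.00111; adjusted p = 0.333 with an estimated correlation) rose with 0 members passing over all genes or adjusted over the list alone. The NF-kB median was 0.021 without vehicle replicate 1, 0.0065 without TEPP-46 replicate 3, 0.11 without TEPP-46 replicate 2 and 0.085 without vehicle replicate 3, and that of the NK transcription factors 0.050 without TEPP-46 replicate 2, 0.049 without TEPP-46 replicate 3 and 0.036 with a pseudocount of 5. Irf9, a subunit of the interferon-activated complex ISGF3, was at 23.3 against 20.5 RPKM, and Tnfaip3, the NF-kB inhibitor A20, at 34.1 against 27.6 RPKM.

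The sterol and fatty acid synthesis list, targets of the SREBP factors, fell, with 29 of 32 members below 0 and a median of -0.21 (camera adjusted p = 1.67e-11; adjusted p = 0.333 with an estimated correlation). None passed over all genes and 10 were lower adjusted over the list alone. Fdft1, squalene synthase, was at 24.3 ± 1.19 RPKM (SD, n = 3) under TEPP-46 and 30.6 ± 0.575 (SD, n = 3) in vehicle, and Mvk, mevalonate kinase, was at 12.8 against 16.4 RPKM. The cytosolic ribosomal protein list fell with 76 of 76 members below 0 and a median of -0.11 (camera adjusted p = 1.67e-11; adjusted p = 0.365 with an estimated correlation), 0 passing over all genes or adjusted over the list alone. Rps19 was at 1055 against 1231 RPKM. The mitosis list fell with 34 of 35 below 0 and a median of -0.18 (camera adjusted p = 1.62e-06; adjusted p = 0.615 with an estimated correlation), likewise with 0 members passing either way. Mki67 was at 128 against 146 RPKM. MYC targets fell with 40 of 40 below 0 and a median of -0.22 (camera adjusted p = 7.36e-05, and 0.651 with an estimated correlation). None of the 40 passed over all genes, adjusted over the list alone or at an unadjusted p under 0.05. The call was lost without TEPP-46 replicate 2 (camera adjusted p = 0.137, median -0.10). The MYC target median was -0.10 without vehicle replicate 3 and -0.33 without vehicle replicate 2. The mitosis median was -0.10 without TEPP-46 replicate 1 and -0.08 without vehicle replicate 2, and the ribosomal protein median -0.06 with quantile normalization. The DNA replication list (27 of 36 below 0, median -0.06, camera adjusted p = 0.240) and the canonical histone genes (13 of 13 below 0, median -0.11, adjusted p = 0.394) did not pass.

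Amino acid supply lists fell too. In the list of ATF4 targets, 16 of 23 members lay below 0 (median -0.09, camera adjusted p = 0.00466; adjusted p = 0.505 with an estimated correlation), with 0 passing over all genes and 5 lower adjusted over the list alone. Asns, asparagine synthetase, was at 20.3 ± 0.730 RPKM (SD, n = 3) under TEPP-46 and 27.7 ± 0.900 (SD, n = 3) in vehicle. In the one-carbon and serine synthesis list, 10 of 12 lay below 0 (median -0.21, adjusted p = 0.00334; adjusted p = 0.505 with an estimated correlation), with 0 passing over all genes and 1 lower adjusted over the list alone. Psat1 and Phgdh, enzymes of serine synthesis from a glycolytic intermediate, were at 70.8 against 84.2 and 106 against 130 RPKM. The tricarboxylic acid cycle list fell (24 of 26 below 0, median -0.09, adjusted p = 0.000550; adjusted p = 0.505 with an estimated correlation) with 0 members passing over all genes or adjusted over the list alone, and the glycolysis list did not pass (15 of 21 below 0, median -0.05, adjusted p = 0.0932). The one-carbon median was -0.11 without TEPP-46 replicate 2, and the tricarboxylic acid cycle median -0.05 without vehicle replicate 3.

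In all, 11 lists rose and 10 fell of 38 tested. T cell markers, a list of another cell type, were among those that rose (6 of 8 above 0, median 0.08, camera adjusted p = 0.0383; adjusted p = 0.333 with an estimated correlation), and the call was lost without vehicle replicate 1, TEPP-46 replicate 1 or TEPP-46 replicate 2 (adjusted p = 0.171, 0.0843 and 0.124) and with median-ratio rescaling (adjusted p = 0.0576). Its median was 0.021 without vehicle replicate 1 and 0.050 with a pseudocount of 5. Trbc1, a T cell receptor constant gene, was at 515 against 460 RPKM. With an estimated correlation no list passed, and 3 passed in fry's directional test. These were the NK receptor, cytotoxic effector and NK transcription factor lists (fry adjusted p = 0.0321, 0.0254 and 0.0179). The sterol and fatty acid synthesis, ribosomal protein, mitosis and MYC target lists did not pass it (fry adjusted p = 0.116, 0.134, 0.418 and 0.507).

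**Figure D3:**
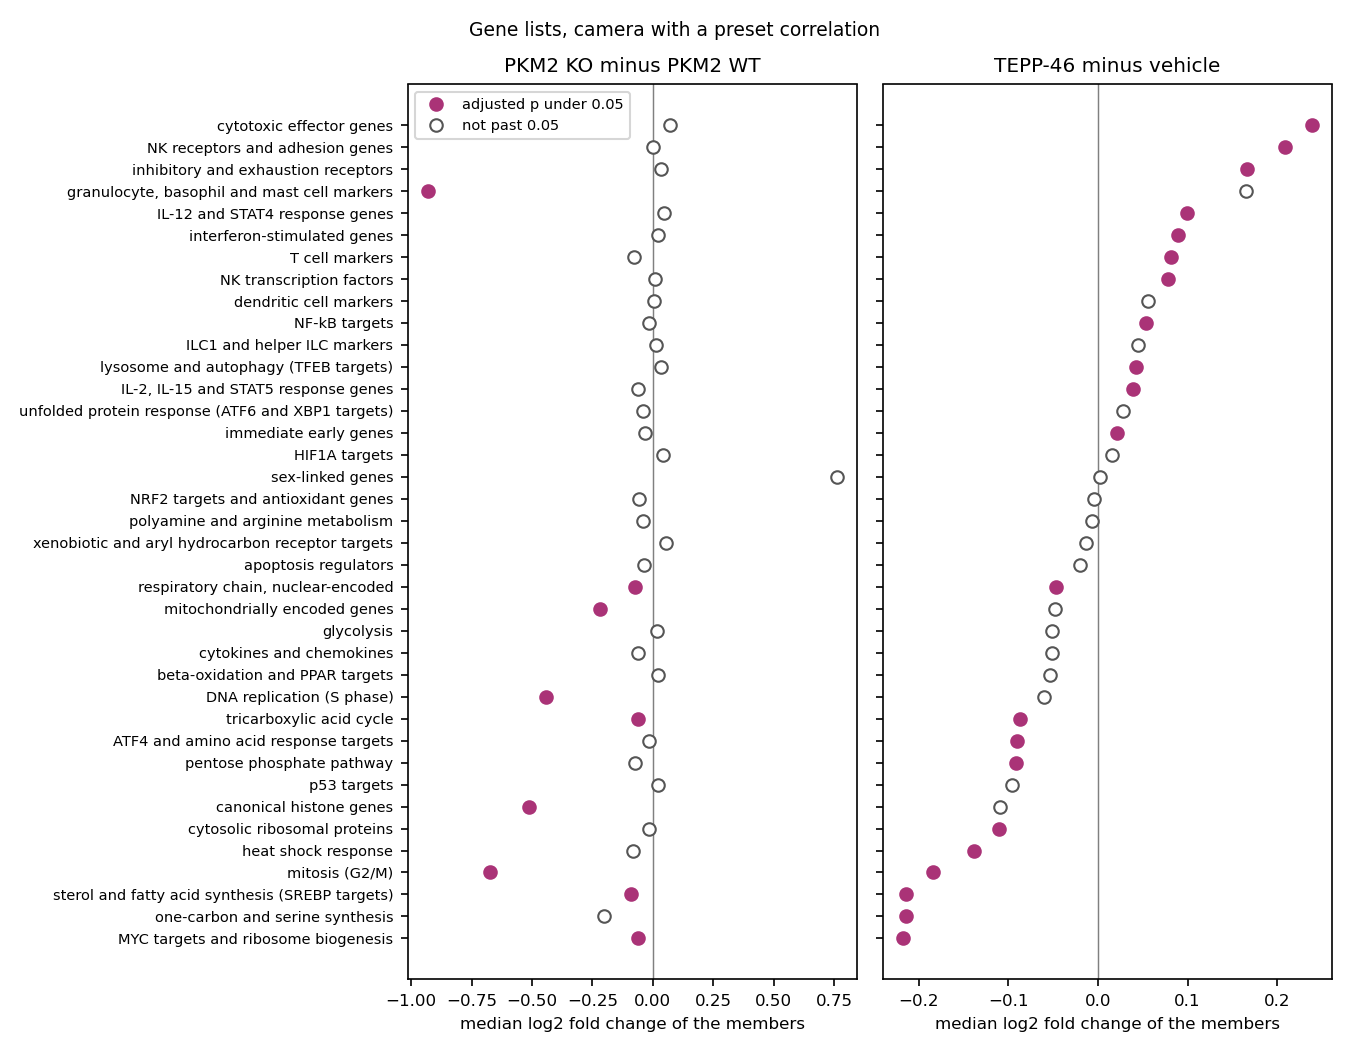
Median log2 fold change of the measured members of each of 38 gene lists, PKM2 KO minus PKM2 WT (left) and TEPP-46 minus vehicle (right), on axes of different range. Filled points are lists past an adjusted p of 0.05 in camera with a preset correlation; the mitosis list lies at -0.67 on the left and the NK receptor list at 0.21 on the right.

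No single gene passed between TEPP-46 and vehicle in limma without pairing of libraries (0 higher and 0 lower of 11142). In that fit 1051 genes had an unadjusted p under 0.05, 529 higher and 522 lower. Chance alone would give about 557. With the replicate number as a block 3 genes passed, all higher, and whether the libraries were paired is undecided. The groups did not overlap in 15.3% of the genes, where chance gives 10%. The genes with the smallest p, which did not pass, were led by the metallothioneins, small metal-binding proteins. Mt1 (ENSMUSG00000031765, chromosome 8, 94179082 to 94180327) was at 118 ± 7.04 RPKM (SD, n = 3) under TEPP-46 and 55.4 ± 4.88 (SD, n = 3) in vehicle, higher in 3 of 3 libraries (log2 fold change 1.08, SE 0.08, limma adjusted p = 0.152). Mt2 (ENSMUSG00000031762, chromosome 8, 94172664 to 94173568) was at 46.9 ± 7.87 against 17.5 ± 0.681 RPKM (log2 fold change 1.36, SE 0.13, limma adjusted p = 0.239). Padi2, a peptidylarginine deiminase, was at 162 against 126 RPKM, and Afp at 2.67 against 4.34 RPKM. Gm44330 was listed at 0 in the 3 TEPP-46 libraries, and Igkv14-111 was at 2.19 against 3.62 RPKM.

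Of 24 genes in the authors' deposited table for TEPP-46, 12 were in the expression table, all 12 in the direction of the authors' deposited table, 11 with an unadjusted p under 0.05 and 0 past the threshold by limma. Mt1 had a ratio of 2.13 in the authors' deposited table and a ratio of mean RPKM of 2.13 here, and Gzmf 3.15 and 3.16. Tnnt1, a troponin gene, was at 2.46 against 4.38 RPKM. Its ratio was 0.440 in the authors' deposited table and 0.562 here, the largest distance among the 12 (0.354 on the log2 scale). Of these 12, 1 passed without TEPP-46 replicate 1, 1 with robust eBayes, 3 with only protein-coding genes tested and 12 with library weights from arrayWeights. Over all genes, 3 passed without vehicle replicate 1 or TEPP-46 replicate 1, 1 without vehicle replicate 2, vehicle replicate 3 or TEPP-46 replicate 3, 1 with a pseudocount of 0.1, 1 with robust eBayes, 3 with only protein-coding genes tested and 1436 (612 higher, 824 lower) with arrayWeights.

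**Figure D4:**
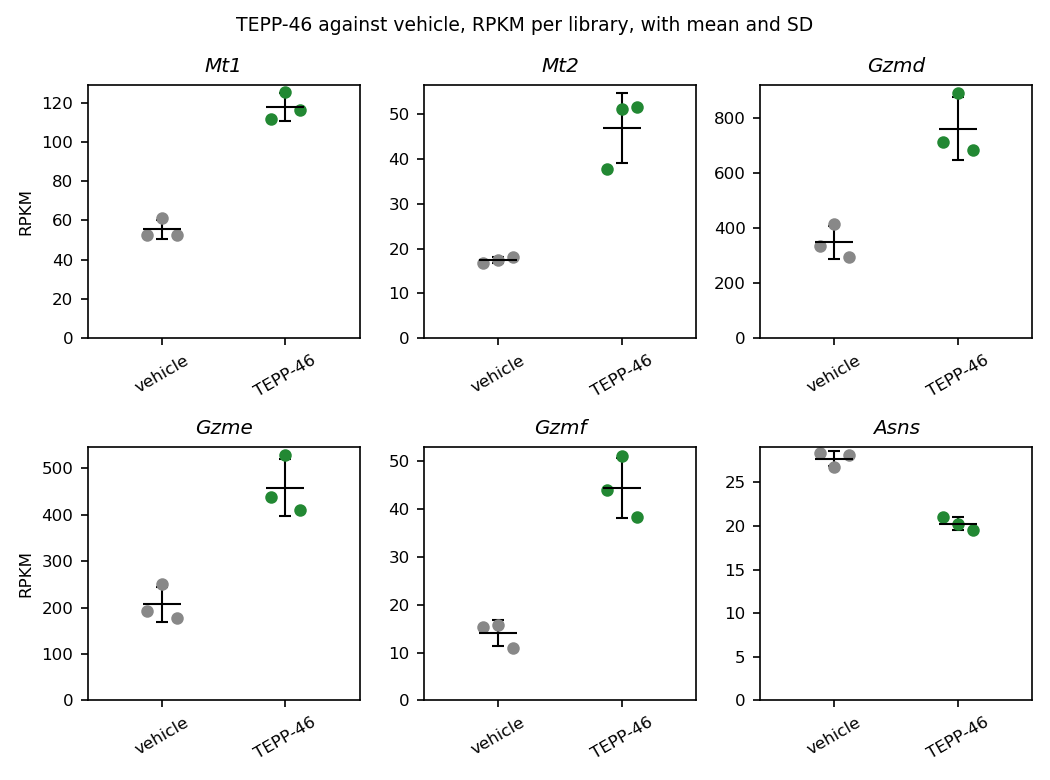
RPKM of Mt1, Mt2, Gzmd, Gzme, Gzmf and Asns in the 3 vehicle and 3 TEPP-46 libraries, one point per library, with the group mean and SD as a bar, on linear axes from 0. The 3 TEPP-46 libraries lie above the 3 vehicle libraries for each gene but Asns, where they lie below.

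The last comparison asks whether activating PKM2 and losing it change opposite or like genes. The 2 effects come from different experiments, with Ifng at 23.4 RPKM in PKM2 WT and 1044 in vehicle. Between these controls 8387 genes differed. How far the effects are alike or differ can therefore not be told apart from the difference between the experiments. Across 11142 genes the effects of PKM2 KO and of TEPP-46, which share no control libraries, correlated weakly, with Pearson's r = 0.0386 and Spearman's rho = 0.206; over the 9680 protein-coding genes r was 0.193 and rho 0.225. Without 1 library r over all genes ran from 0.00239 (TEPP-46 replicate 2) and 0.00598 (vehicle replicate 2) over 0.0134 (PKM2 WT replicate 1), 0.0141 (TEPP-46 replicate 3) and 0.0245 (PKM2 KO replicate 1) to 0.0673 (vehicle replicate 1) and 0.0876 (TEPP-46 replicate 1), and it was 0.0181 with a filter at 5 RPKM. These are correlations across genes, which are not independent replicates. Among genes with an unadjusted p under 0.05, 34 were higher in both where independent lists would share 12.8, and 47 were lower in both where they would share 28.9. Opposite directions were shared by 8 genes (12.6 for independent lists) and 10 genes (29.2). Mki67 was lower in both, by a log2 fold change of -0.57 in PKM2 KO and -0.20 under TEPP-46. The effects themselves differed in 6 genes by limma, 5 of them with the higher log2 fold change under TEPP-46: Slc15a2, Mir6374, Pkm, Cd3g and Pim2, and 1 with the lower, Amica1. The count was 3 without PKM2 WT replicate 2 or vehicle replicate 1, 4 without vehicle replicate 2, vehicle replicate 3 or TEPP-46 replicate 3, and 12 without PKM2 KO replicate 2 (5 with the higher and 7 with the lower log2 fold change under TEPP-46), a fit with 1 PKM2 KO library. It was 10 with a pseudocount of 0.1 and 59 with library weights from arrayWeights.

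**Figure D5:**
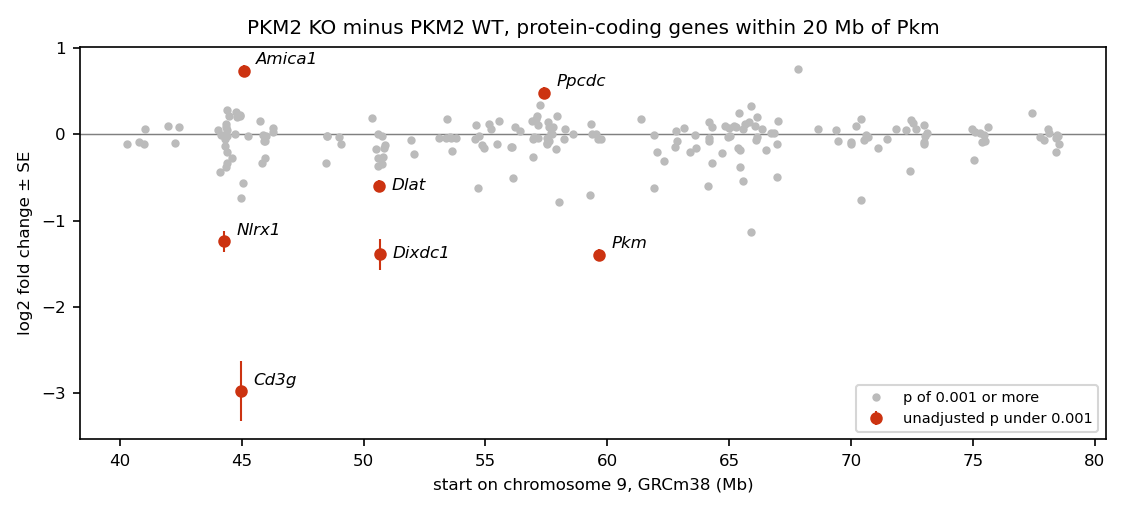
Log2 fold change, PKM2 KO minus PKM2 WT, of protein-coding genes that start within 20 Mb of Pkm, against their start on chromosome 9 (GRCm38, Mb). Red points with SE bars are the genes with an unadjusted p under 0.001, with Cd3g at -2.98 and Amica1 at 0.74.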

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

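The comparisons of ratios with the authors' deposited tables, the share of genes on one side, the scan around Pkm, the T cell and sex checks, the granzyme difference and the value of Slc30a1 were tests chosen only after the result was seen.

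The effects of TEPP-46 and of PKM2 KO differed in 6 genes by limma's test of the difference itself. As the effects come from different experiments, these differences cannot be told apart from one between the experiments. The TEPP-46 effect exceeded the PKM2 KO effect by 5.27 (log2) for Slc15a2, 3.03 for Cd3g, 1.42 for Pkm and 0.57 for Pim2, a survival kinase gene, and the difference was -0.98 for Amica1. Cd3g was at 85.0 RPKM in PKM2 WT and at 10.5 in PKM2 KO, 7.90 in vehicle and 8.25 under TEPP-46, so PKM2 WT stood apart from the other groups. Slc15a2 was at 0.0900 RPKM in PKM2 KO, so its difference depends on the pseudocount, its PKM2 KO value being -7.54 with a pseudocount of 0.1 and -2.99 with 5. Mir6374 was listed at 0 in all libraries but those of PKM2 WT, so its fitted difference of 4.32 is set by the pseudocount of 1 and is no fold; its fitted PKM2 KO value of -4.32 became -7.57 with a pseudocount of 0.1 and -2.27 with 5.

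The libraries labelled PKM2 WT and PKM2 KO lay far from the vehicle libraries in Ifng, Il2ra and Gzmb although all are labelled as cultured with IL-2 and IL-12. A single scale factor from RNA composition would move genes one way, whereas 48.7% of the genes that differed between PKM2 WT and vehicle were higher. That share was 46.1% with only protein-coding genes tested and 43.7% with a filter at 5 RPKM. A difference in composition or library preparation that moves some kinds of RNA up and others down is not excluded by these shares. Libraries that hold unstimulated cells are a candidate explanation that stays open. Ratios of PKM2 KO to PKM2 WT were compared with those in the authors' deposited table over 7 genes. Their mean absolute log2 distance was 0.163 to the unstimulated and 0.401 to the stimulated comparison, but the medians were 0.0880 and 0.0753. Nearer to the unstimulated one lay 3 genes (Pkm, Dixdc1 and Slc37a4), and 4 lay nearer to the stimulated one. Of these 4, Nlrx1 and Rnf26 tell little, as the authors' stimulated and unstimulated ratios lie close together (0.186 and 0.195, 0.660 and 0.621). Distances to the unstimulated and stimulated comparison were 0.0880 and 1.10 for Dixdc1, 0.00463 and 1.04 for Slc37a4 and 0.0738 and 0.518 for Pkm. For Cd3g they were 0.467 and 0.0381, and for Amica1 0.275 and 0.0247, the other way. The Cd3g ratio rests on PKM2 KO values of 14.6 and 6.43 RPKM. A difference between the 2 experiments as the whole cause stays open as well. PKM2 KO replicate 3 was not analysed, so the reach of a further PKM2 KO library was checked. At no value could it bring Dixdc1 and Slc37a4, 2 of the 7 genes, to their ratio in the authors' stimulated comparison. For the authors' unstimulated comparison this held for 0 of the 7. Still, 2 genes and ratios whose computation is not given do not decide it. The ratio of vehicle to PKM2 WT had the direction of WT stimulation in the authors' deposited table in 6 of the 7 (5.27 against 5.78 for Pkm). Of the 10 splits of the 6 libraries of PKM2 WT and vehicle, the real one gave 8387 genes and the highest other 2, and 10 splits are too few for a share under 0.05.

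Genes with a small p between PKM2 KO and PKM2 WT were more frequent near Pkm than elsewhere, although of the 11 genes past the threshold only Pkm itself lies there. Of 204 protein-coding genes within 20 Mb of Pkm, 6 had an unadjusted p under 0.001 (Cd3g, Nlrx1, Dixdc1, Dlat, Amica1 and Ppcdc, limma adjusted p from 0.108 to 0.333), against 7 of 9475 elsewhere (Fisher's exact p = 1.24e-07, which treats genes as independent), and 0 of 204 did under TEPP-46. Fewer T cells would lower other T cell markers as much as Cd3g, provided that the NK cells do not express these markers themselves. The median log2 fold change of the 6 measured markers other than the CD3 genes was 0.0274, with a range from -0.29 to 0.27. Whether the NK cells express these 6 was not tested, so their values do not exclude fewer T cells. Cd3d, which lies beside Cd3g and was left out with it, was at -0.74 (SE 0.35). With sex as a covariate, which leaves 1 residual degree of freedom fewer, Cd3g had a log2 fold change of -2.94 (SE 0.37) with an unadjusted p of 0.00139, and 2 of the 204 genes (Nlrx1 and Amica1) had an unadjusted p under 0.001, against 6 of 9475 elsewhere (Fisher's exact p = 0.0114). A segment of chromosome 9 linked to the targeted allele, from another strain, may account for the 6 genes, as a hypothesis that leaves out Slc15a2 on chromosome 16; an effect of losing PKM2 on them was not tested apart from it.

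Mt1, Mt2 and Gzmf had the smallest p under TEPP-46, and Gzmd and Gzme shifted with them, none past the threshold. Reads of 1 granzyme gene spread over all its neighbours would give them like fold changes. The log2 fold change of Gzmf exceeded that of Gzmc by 1.36 (SE 0.19) and that of Gzmd by 0.47 (SE 0.10). Partial sharing among Gzmd, Gzme, Gzmf and Gzmg, with log2 fold changes of 1.13, 1.15, 1.60 and 1.23, is not excluded by this. A response to zinc or another metal is a candidate explanation for Mt1 and Mt2: Slc30a1, a zinc exporter that metal induces and also listed in the authors' deposited table, was at 3.93 ± 0.437 RPKM against 2.44 ± 0.275 (SD, n = 3 each; log2 fold change 0.52), without overlap between the groups, but it did not pass (limma adjusted p = 0.319) and 15.3% of all genes did not overlap either, so the support is weak. Whether the metal, the compound or the activated enzyme is involved was not tested. With 0 genes in the real split, each of the 10 splits of the 6 libraries gives at least as many whatever the data (the highest other gave 6), so their count says nothing about chance.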

How the results depend on the processing

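Protein-coding genes only, sex as a covariate, and the further settings for the lists and the authors' genes were chosen after seeing the data; causes were not tested except where fewer genes or libraries were used. Genes that differed between PKM2 KO and PKM2 WT numbered 11, and 7 with a pseudocount of 5, 25 with the spread from all 11 libraries, 6 with sex as a covariate, and 5 to 21 without 1 library. For TEPP-46 against vehicle 0 became 1 with a pseudocount of 0.1, 1 with robust eBayes, 1436 with arrayWeights, 3 with protein-coding genes only, and 0 to 3 without 1 library. For the difference of the effects 6 became 10 with a pseudocount of 0.1, 59 with arrayWeights, and 3 to 12 without 1 library. PKM2 WT against vehicle gave 5019 genes at 1.5-fold or more in place of 8387, and 7945 to 8250 without 1 library.

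The replicate number as a block gave 0 genes for PKM2 KO, 3 for TEPP-46 (2597 in place of 1051 at an unadjusted p under 0.05), 3 for the difference of the effects and 0 and 3 of the authors' genes; Pkm had a log2 fold change of -1.42 with the block (limma adjusted p = 0.267), -1.39 with sex as a covariate and -1.42 to -1.35 without 1 library (-1.35 without PKM2 WT replicate 1); its adjusted p lay between 0.000120 and 0.267 over all settings. PKM2 KO replicate 3 was not analysed, so with the block PKM2 WT replicate 3 did not inform the PKM2 KO effect. Pkm had the same log2 fold change of -1.42 without that library (limma adjusted p = 0.0465). The block also leaves fewer residual degrees of freedom, so the lost PKM2 KO calls say nothing about pairing. Among the gene lists the block ended 1 call for PKM2 KO (mitochondrially encoded genes, adjusted p = 0.0761) and added 2 (one-carbon and serine synthesis, 0.0267, and cytosolic ribosomal proteins, 0.0279). For TEPP-46 it ended 0 and added 4 (canonical histone genes, adjusted p = 7.27e-05, granulocyte, basophil and mast cell markers, 0.00190, glycolysis, 0.0462, and the unfolded protein response, 0.0483). The labels do not say that a number pairs samples, and the numbers were not taken as pairs: deviations of same-numbered TEPP-46 and vehicle libraries correlated at 0.0523, 0.284 and 0.275, each TEPP-46 library best with its own number, a hint that leaves pairing undecided there, and those of PKM2 KO and PKM2 WT at 0.0702 and -0.0967.

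Of the authors' genes, 1 was called for PKM2 KO, and 2 with robust eBayes, 3 with arrayWeights, 5 with the spread from all libraries, 5 with protein-coding genes only, 0 with sex as a covariate and 0 to 1 without 1 library. For TEPP-46 0 became 1 with robust eBayes, 12 with arrayWeights, 3 with protein-coding genes only and 0 to 1 without 1 library. Lists past the threshold numbered 9 for PKM2 KO and 21 for TEPP-46, and 0 and 0 with an estimated correlation, and 0 and 3 with fry. The correlation of the effects was 0.0386, 0.193 with protein-coding genes only, and 0.00239 (without TEPP-46 replicate 2) to 0.0876 (without TEPP-46 replicate 1) without 1 library. Of the genes and lists called in the 4 comparisons, 10 genes of PKM2 WT against vehicle passed in the opposite direction with quantile normalization, and none did in the other settings run. The unknown depth limits low genes most.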

Other observations

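Further lists rose or fell under TEPP-46 by small amounts. Inhibitory and exhaustion receptors rose (10 of 13 members above 0, median log2 fold change 0.17, camera adjusted p = 0.00820; adjusted p = 0.336 with an estimated correlation), with 0 passing over all genes and 2 higher adjusted over the list alone. Cd96 was at 68.6 RPKM under TEPP-46 and 57.2 in vehicle, and Havcr2, the receptor TIM-3, at 40.2 against 33.5 RPKM. The list was lost without TEPP-46 replicate 2 (adjusted p = 0.131, median 0.086), and its median was 0.098 without vehicle replicate 3 and 0.094 with a pseudocount of 5. IL-12 and STAT4 response genes rose with 17 of 22 above 0 (median 0.10, adjusted p = 0.00267; adjusted p = 0.333 with an estimated correlation), a call lost without TEPP-46 replicate 1 (adjusted p = 0.0578), with 0 passing over all genes and, adjusted over the list alone, 5 higher and 1 lower. Its median was 0.043 without TEPP-46 replicate 2 and 0.042 without vehicle replicate 3. The IL-2, IL-15 and STAT5 response list rose with 18 of 28 above 0 (median 0.04, adjusted p = 0.0248; adjusted p = 0.333 with an estimated correlation), with 0 passing over all genes and, adjusted over the list alone, 4 higher and 1 lower. It was lost without TEPP-46 replicate 1 (adjusted p = 0.212) and with median-ratio rescaling (adjusted p = 0.0814), and its median was 0.025 without vehicle replicate 1, 0.062 without TEPP-46 replicate 3 and 0.059 with quantile normalization. Bcl2, a survival gene of the IL-2 and STAT5 list, was at 54.7 ± 1.00 against 43.9 ± 2.12 RPKM (SD, n = 3 each; limma adjusted p = 0.316), and Tnfrsf9, the costimulatory receptor 4-1BB, at 594 against 468 RPKM.

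Lysosome and autophagy genes rose (20 of 26 above 0, median 0.04, camera adjusted p = 0.0130, and 0.333 with an estimated correlation). Immediate early genes, a list fixed among those of RNA quality, rose as well (13 of 21, median 0.02, camera adjusted p = 0.0141, and 0.336 with an estimated correlation). No member of either passed over all genes, and 0 and 3 were higher adjusted over the list alone. The former was lost without TEPP-46 replicate 2 (adjusted p = 0.157, median 0.013), and its median was 0.072 without TEPP-46 replicate 3 and 0.073 with quantile normalization. The latter was lost without TEPP-46 replicate 1 or vehicle replicate 3 (adjusted p = 0.211 and 0.0513), with a median of -0.0074, on the other side of 0, and 0.012. Its median was 0.087 without vehicle replicate 2, 0.075 without TEPP-46 replicate 3, 0.15 with a filter at 5 RPKM, 0.036 with median-ratio rescaling and 0.053 with quantile normalization. The heat shock list fell (12 of 13 below 0, median -0.14, adjusted p = 0.0347; adjusted p = 0.651 with an estimated correlation), as did the pentose phosphate list (9 of 10, median -0.09, adjusted p = 0.0256; adjusted p = 0.505 with an estimated correlation) and the nuclear-encoded respiratory chain list (51 of 71, median -0.05, adjusted p = 0.0119; adjusted p = 0.651 with an estimated correlation). No member of these 3 passed over all genes, and only 1 heat shock gene passed, higher, adjusted over the list alone. Each was lost without TEPP-46 replicate 1 (adjusted p = 0.0740, 0.0834 and 0.146; median -0.030 for the respiratory chain). The heat shock and pentose phosphate lists were also lost without TEPP-46 replicate 2 (adjusted p = 0.246 and 0.0759) or vehicle replicate 3 (adjusted p = 0.213 and 0.0560, median -0.07 and -0.05), and the heat shock list with a filter at 5 RPKM (adjusted p = 0.0978) or quantile normalization (adjusted p = 0.0506). The respiratory chain list was lost without vehicle replicate 2 or TEPP-46 replicate 3 (adjusted p = 0.327 and 0.183) and with median-ratio rescaling (adjusted p = 0.0519). The heat shock median was -0.09 without TEPP-46 replicate 2, -0.25 without vehicle replicate 2 and -0.26 without TEPP-46 replicate 3, and the respiratory chain median -0.07 without TEPP-46 replicate 2 and -0.030 with quantile normalization.

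In the libraries labelled PKM2 KO, the granzymes Gzmd, Gzme, Gzmf and Gzmg were at 690, 336, 49.0 and 113 RPKM against 496, 250, 29.8 and 74.0 in PKM2 WT, none past the threshold (limma adjusted p = 0.565, 0.573, 0.565 and 0.573). Their log2 fold changes lay above 0 in both comparisons. All 6 libraries of the drug experiment expressed Ddx3y, between 33.4 and 37.1 RPKM, and Xist at 0.0200 RPKM or less.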
